A study of Mus musculus and Macaca nemestrina with 20 samples.

How the data were processed

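Bulk RNA sequencing of dorsal root ganglia was analysed for 20 libraries: 14 from mice and 6 from pig-tailed monkeys. Per the labels' protocols, total RNA was purified from fresh frozen ganglia with the Direct-zol kit, and libraries were made and sequenced at a core facility. The labels do not state whether the library preparation kept strand, so reads of overlapping and antisense genes cannot be told apart.

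The authors deposited 2 kinds of table for each species. The first holds estimated counts per gene, which need not be whole numbers, and the second holds TPM, a share of transcripts scaled for transcript length, per gene. The authors made the estimated counts with kallisto and summed them to genes before they were deposited, per the labels' processing notes and the gene names of the tables. Per the submitters' processing notes, kallisto, which assigns reads to transcripts by pseudoalignment, was used, and the genome build named is GRCm38; the kallisto version is not given in the sources used here. The same mouse build is written on the monkey samples, and the transcriptome used for the monkeys is not given in the sources used here. kallisto divides reads between similar transcripts, so values of pseudogenes and close paralogs are uncertain. The deposited mouse TPM columns sum, in units of 1000, to between 601 and 834 in batch 1 and between 954 and 979 in batch 2, while each monkey column sums to 1000. Mouse TPM levels are therefore not on the same scale in both batches. Within batch 1 the scale also differs by genotype, with sums of 601 to 797 in flox and 787 to 834 in knockout. Means over all 7 libraries of a genotype pool the batches and are given as levels. The main tests rest on counts with batch in the model, while the permutation test of Nppb and the limma alternatives rest on TPM.

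The mouse tables hold a row that names no gene. It took 0.0785% to 0.186% of the estimated counts of each library and was left out of library totals and tests. Estimated counts were rounded to whole numbers. This left 29766 mouse genes, and the monkey tables held 35194 genes. Every column of the tables was matched to a sample by its library name. No pair of libraries within a group held identical counts, and chi-square per gene between libraries of a group was at least 22.1 in mice and 29.0 in monkeys, where sampling noise alone gives about 1. The monkey minimum belonged to SADBE libraries 2 and 3, while the other monkey pairs lay between 297 and 558. These values show that no library is a copy of another. They do not show that the libraries came from different animals. Each library was counted as a replicate. The labels do not say how many animals made up a library, so p-values measure the spread between libraries.

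Groups, batches and replicate numbers were taken from the labels. In mice, 7 libraries labelled ADAM17 knockout were compared with 7 labelled flox. In monkeys, 3 libraries from ganglia of skin treated with squaric acid dibutyl ester (SADBE) were compared with 3 of vehicle-treated skin. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr (minimum count 10, minimum total count 15) and TMM scaling, with robust dispersion estimates. Batch was a term of the mouse model. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. Benjamini-Hochberg adjusted p-values under 0.05 were called. An interaction of batch and genotype was tested in the same way. Nppb was also tested with an exact two-sided permutation test on log2(TPM + 1), permuting genotype within batch in mice.

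Of 30 gene lists written from textbook knowledge before the data were examined, 1 (sex-linked genes) was kept out of the list tests. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, which gave 29 lists in mice and 25 in monkeys, and again with a correlation estimated from the data. fry, a self-contained test of the same package, was an alternative. Counts of changed members are given over all genes tested and, where stated, adjusted over the list alone.

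The genes named were set by a rule fixed before the data were examined. It takes Nppb, Adam17 and every tested member of the list of NP3 pruriceptor genes. It adds the 10 largest log2 fold changes in each direction among called genes with a mean of at least 1 TPM in the higher group and the same sign in both batches; in monkeys, non-overlapping groups replaced the batch condition. Where no gene passed, the 5 lowest p-values in each direction were taken. Up to 4 members with the lowest p were named for each list, and up to 10 genes called in the same direction in both species. Predicted genes with Gm, Rik or LOC identifiers were not counted as having an official symbol. Mouse coordinates come from the GENCODE M21 annotation of GRCm38, in which all 28 mouse genes of the rule were found by symbol. No coordinates are given for monkeys.

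Genes were matched between species by identical symbol in capitals, which left 12213 genes tested in both. Overlaps were tested with Fisher's exact test against the number expected of independent lists.

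The scripts were tested on simulated data drawn from the real means, library sizes and dispersions. In the simulated mouse comparison (15419 genes), edgeR recovered 28.4% of the genes changed 1.5-fold, 68.7% of those changed 2-fold and 98.5% of those changed 4-fold, with 4 false calls among 139. In the simulated monkey comparison (17304 genes), edgeR recovered 0% at each of these sizes, while DESeq2 recovered 33.3% of the 4-fold genes with 26 false calls among 51.

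The alternatives fixed before the data were examined were: DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), voom with quality weights, RLE size factors, other filters on low counts, adjusted p limits of 0.01 and 0.1, no batch term, each batch alone, the replicate number as a block, and leaving out each library. A sex term was also planned for the case that sex-linked genes showed both sexes in both groups. It was not run: Y-linked genes stood clearly above the other libraries in 2 knockout libraries and in no flox library, and no sex-linked gene of the list could be tested in monkeys. Alternatives chosen after seeing the data were leaving out knockout libraries in pairs and thinning every mouse library to the smallest total.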

Results

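Dorsal root ganglia (DRG), which hold the cell bodies of the sensory neurons of skin and muscle, were profiled by bulk RNA sequencing in 2 settings that the series title places under chronic itch. The first was a mouse line labelled as a knockout of ADAM17, a membrane protease that sheds cytokines and growth factor ligands from the cell surface, with 7 libraries, set against 7 libraries labelled flox. The second was the pig-tailed monkey (Macaca nemestrina), with 3 libraries from DRG of skin treated with squaric acid dibutyl ester (SADBE), a contact sensitiser, and 3 of vehicle-treated skin. The mouse labels give a batch: batch 1 held 4 knockout and 3 flox libraries, and batch 2 held 3 knockout and 4 flox libraries. Batch 1 differed in depth between genotypes, with 12.1 to 14.7 M counts (M, 1e6) in knockout and 46.9 to 52.1 M in flox libraries. In batch 2 the totals were 27.9 to 30.8 M and 30.9 to 36.0 M. Monkey totals ran from 9.02 to 22.4 M for SADBE and from 13.7 to 27.1 M for vehicle. The mitochondrial share of counts was 8.21% to 8.70% in knockout and 8.22% to 10.9% in flox libraries of batch 1. In batch 2 it was 0.734% to 1.03% in knockout and 1.40% to 1.76% in flox libraries, without overlap.

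The targeted gene, Adam17 (GRCm38 chromosome 12, 21323509 to 21373632, minus strand), was detected at similar levels in both genotypes. In flox libraries 1 to 7 it stood at 6.07, 6.43, 5.88, 9.51, 5.75, 8.16 and 8.47 TPM. In knockout libraries 1 to 7 it stood at 7.27, 4.70, 6.23, 8.28, 7.76, 7.32 and 9.18 TPM. The log2 fold change was 0.03 ± 0.18 (SE), and the adjusted p of edgeR's quasi-likelihood test was 0.930. The labels do not give the tissue or the exons in which the floxed gene was deleted, so the gene-level value in DRG does not check the genotype. Knockout and flox below are the genotypes as labelled.

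The first comparison asks whether Nppb, which encodes the itch neuropeptide natriuretic polypeptide b, and other DRG transcripts differ between knockout and flox mice. Nppb was about 3-fold higher in knockout DRG, and other receptors and peptides of the same pruriceptor neurons rose with it. Genes of neutrophil granules, of the acute-phase response and of injured sensory neurons rose as well. Of the fibroblast and matrix genes 9 of 10 fell, as did 5 of 10 myelin genes and 5 of 14 clock genes, while 1 clock gene rose. These 3 lists were lower at camera's preset correlation and not with an estimated correlation (adjusted p of 0.115, 0.270 and 0.150). edgeR's quasi-likelihood test called 2423 of 15654 genes, 1248 higher and 1175 lower in knockout, of which 871 differed by more than 2-fold.

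Nppb (chromosome 4, 147985788 to 147987205, plus strand) rose by 1.66 ± 0.19 (log2 fold change ± SE; 3.16-fold), with an adjusted p of 4.61e-05. In batch 1 it averaged 213.6 ± 17.6 TPM (SD, n = 4) in knockout and 70.0 ± 0.548 TPM (SD, n = 3) in flox. In batch 2 it averaged 59.1 ± 16.5 TPM (SD, n = 3) in knockout and 17.9 ± 4.72 TPM (SD, n = 4) in flox. The log2 fold change was 1.43 ± 0.21 within batch 1 and 1.87 ± 0.30 within batch 2, with adjusted p-values of 0.0149 and 0.00415 in edgeR. Within each batch every knockout library was above every flox library. An exact two-sided permutation test within batches gave p = 0.000816, the smallest its 1225 splits allow.

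**Figure D1:**
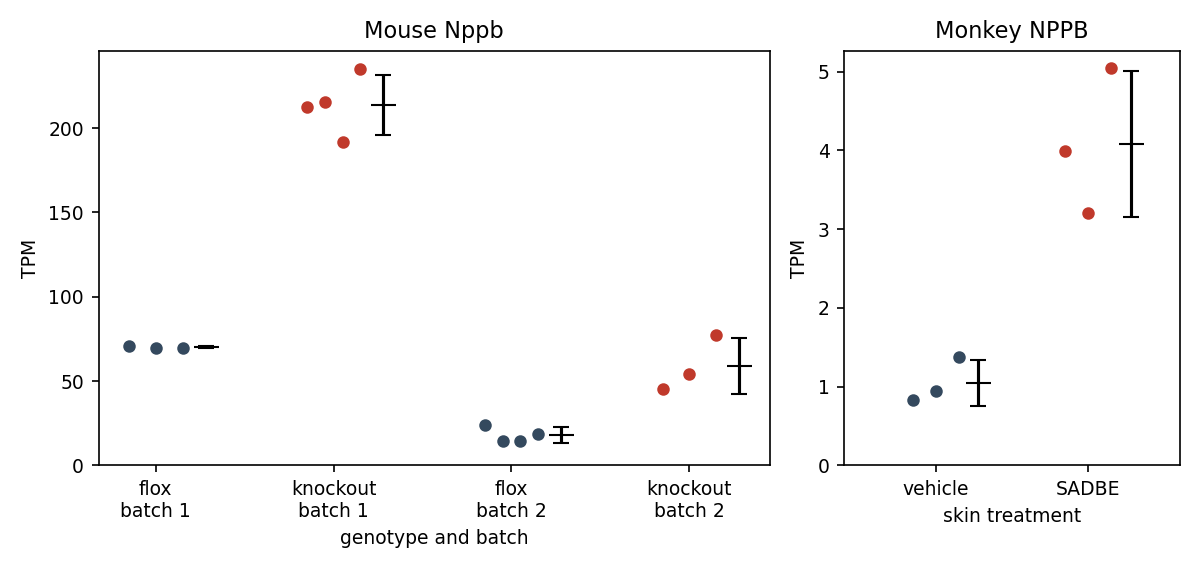
Nppb in mouse DRG (left) and NPPB in monkey DRG (right), in TPM on linear axes; each point is a library, and the black marks beside the points are the mean and SD of the group. In batch 1 the mouse means were 213.6 TPM in knockout and 70.0 TPM in flox, and in monkeys the means were 4.08 TPM with SADBE and 1.05 TPM with vehicle.

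Nppb belongs to the NP3 class of itch-sensing neurons, and 6 of the 7 tested NP3 genes rose, both over all genes and adjusted over the list alone. Il31ra, the receptor of the itch cytokine interleukin 31 (chromosome 13, 112519898 to 112594360), rose from 4.37 ± 1.26 to 15.4 ± 7.83 TPM (SD, n = 7 each), a log2 fold change of 1.79 ± 0.24. Osmr, the oncostatin M receptor subunit that pairs with it, rose by 1.29 ± 0.17, and Cysltr2, a cysteinyl leukotriene receptor, by 1.54 ± 0.25. Their adjusted p-values were 0.000156, 0.000171 and 0.000735 in edgeR. Nts, encoding neurotensin, rose by 1.73 ± 0.30 over both batches, but its change differed between them (interaction 1.82 ± 0.36, adjusted p = 0.0264), and it was not called in batch 1 alone (0.80 ± 0.27, adjusted p = 0.169). Htr1f, a serotonin receptor, rose by 0.82 ± 0.22. Htr1f was called with an adjusted p of 0.0188 and was no longer called without knockout library 5 (adjusted p = 0.0700) or within either batch alone. Sst, encoding somatostatin, did not pass (-0.35 ± 0.36, adjusted p = 0.545). The list as a whole was called by camera, with an adjusted p of 1.80e-08 at the preset correlation and an adjusted p = 0.00368 with an estimated correlation.

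Among the genes with the largest rises, several were close to undetected in flox DRG. Cyp26a1, which degrades retinoic acid (chromosome 19, 37697798 to 37701536), stood at 53.5 ± 19.9 TPM in knockout and 0.115 ± 0.186 TPM in flox (SD, n = 7 each). Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, stood at 11.1 ± 4.69 and 0.219 ± 0.154 TPM. Accsl rose by 5.73 ± 0.55 on the log2 scale, and Sprr1a, a small proline-rich protein induced in axotomised neurons, by 6.04 ± 0.65. Ighg1, the constant region of an immunoglobulin heavy chain, rose from 0.147 to 24.6 TPM, with 118.4 TPM in knockout library 6 and 1.01 TPM in knockout library 1. Serpina3m stood at 3.61 TPM in knockout, and 5 of the 7 flox libraries held no count of it; it belongs to a cluster of near-identical paralogs, which makes its value uncertain. Fezf2, a transcription factor, stood at 1.03 ± 0.426 TPM in knockout, and its flox libraries held no count except for 4 counts in library 6, so no fold is given. The processed pseudogenes Ftl2-ps and Rps19-ps6 were also called, with means of 350.9 and 119.3 TPM in knockout. Both calls were lost with limma on log2(TPM + 0.1), with voom and without knockout libraries 6 and 7 (adjusted p up to 0.400 and 0.262). Both can share reads with their parent genes and are uncertain: Ftl2-ps ranged from 0.496 TPM in knockout library 4 to 1214.0 TPM in knockout library 6.

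The 10 genes with the largest falls included genes of the extracellular matrix. Mfap4, a microfibril protein (chromosome 11, 61485431 to 61488900), fell by 3.86 on the log2 scale, from a mean of 11.7 to 1.37 TPM (n = 7 each). Col2a1, a cartilage collagen, and Chad, a cartilage matrix protein, had log2 fold changes of -3.62 ± 0.64 and -3.03 ± 0.51. Sfrp4, a secreted Wnt antagonist, and Igf2, a growth factor, had log2 fold changes of -3.04 ± 0.56 and -2.72 ± 0.42, with Igf2 at 14.3 TPM in knockout and 90.8 TPM in flox. Krtdap, a keratinocyte protein, had a log2 fold change of -4.00 ± 0.56, and Hal, the enzyme that deaminates histidine, one of -3.51 ± 0.53. Otoa, Gxylt2 and Cma1, a mast cell chymase, also fell, with log2 fold changes of -3.69, -3.39 and -2.70. The adjusted p-values of these 10 genes lay between 4.64e-05 and 0.0103 in edgeR.

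Among the lists fixed before the data were examined, the neutrophil and marrow genes showed the largest rise, with 9 of 10 called (also 9 adjusted over the list alone). S100a8 and S100a9, which encode the calprotectin subunits, stood at 2670 and 1651 TPM in knockout against 264.9 and 172.3 TPM in flox. Their log2 fold changes were 3.12 ± 0.37 and 3.19 ± 0.38, with an adjusted p of 9.83e-05 for each. Retnlg and Ngp, both granulocyte genes, rose by 2.89 ± 0.38 and 3.10 ± 0.42. The erythroid list, which reports blood in the tissue, had no called gene out of 6 (camera adjusted p = 0.974), and its mean level was highest in knockout library 4, at 11.3 on the log2(TPM + 1) scale. camera's adjusted p for the neutrophil list was 3.27e-17, and the adjusted p = 0.0416 with an estimated correlation.

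Acute-phase and inflammation genes rose in 8 of 14 tested members, and 9 passed when adjusted over the list alone. Socs3, the feedback inhibitor of cytokine signalling through STAT3, rose by 2.00 ± 0.13, with an adjusted p of 1.04e-07. Serpina3n, a protease inhibitor, rose by 2.61 ± 0.18, from 50.6 to 295.0 TPM. Lcn2, encoding lipocalin 2, and Lrg1 rose by 3.46 ± 0.35 and 2.68 ± 0.33. The list's adjusted p was 1.06e-13 by camera, with an adjusted p = 0.00648 with an estimated correlation. Of the nerve injury genes, 7 of 13 rose and 1 fell (9 adjusted over the list alone). Sox11, a transcription factor of axon regrowth, rose by 2.92 ± 0.24, and Gadd45a and Atf3, stress-response genes of injured neurons, rose by 0.84 ± 0.11 and 1.77 ± 0.24. Sox11 (chromosome 12, 27334264 to 27342574) lies within 20 Mb of Adam17, where strain variants carried along with the targeted gene may account for some calls. camera gave this list an adjusted p of 1.80e-08, with an adjusted p = 0.00380 with an estimated correlation.

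Peptidergic nociceptor genes rose in 4 of 8 cases (4 adjusted over the list alone). These were Tac1, encoding substance P, Calca, encoding calcitonin gene-related peptide, and the ion channels Trpv1 and Trpa1. Their log2 fold changes were 0.78 ± 0.11, 0.80 ± 0.12, 1.16 ± 0.19 and 1.35 ± 0.31. The list's camera adjusted p of 7.51e-05 was lost with an estimated correlation (adjusted p = 0.119). Of the cytokine receptor and signalling genes, 5 of 18 rose and 1 fell (7 adjusted over the list alone). Il4ra and Il13ra1, receptor chains of interleukins 4 and 13, rose by 1.93 ± 0.19 and 1.48 ± 0.19, and the kinase Jak1 rose by 0.66 ± 0.12. Il6st, the shared receptor chain gp130, had a log2 fold change of -0.62 ± 0.11. camera's adjusted p was 0.00735, with an adjusted p = 0.129 with an estimated correlation. Cell cycle genes rose in 2 of 10 cases (3 adjusted over the list alone), Ccnb1 by 1.42 ± 0.37 and Bub1 by 1.99 ± 0.56. That list had an adjusted p of 0.0113 by camera, an adjusted p = 0.588 with an estimated correlation, and was not called without knockout library 5 (adjusted p = 0.0764).

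Fibroblast and matrix genes fell in 9 of 10 cases (10 adjusted over the list alone). Col1a1, the main collagen of connective tissue, had a log2 fold change of -2.04 ± 0.26, from 53.8 to 11.3 TPM. Col5a1, Col1a2 and Col3a1 had log2 fold changes of -1.78 ± 0.24, -1.61 ± 0.22 and -1.58 ± 0.27. camera's adjusted p for the list was 1.29e-11, and it was not called with an estimated correlation (adjusted p = 0.115). Myelin genes fell in 5 of 10 cases (6 adjusted over the list alone): Prx by 1.18 and Mbp by 0.86 on the log2 scale, with SEs of 0.23 and 0.17, and Mag with a log2 fold change of -0.94. The list's camera adjusted p was 0.000158, with an adjusted p = 0.270 with an estimated correlation. Clock genes fell in 5 of 14 cases and rose in 1 (8 adjusted over the list alone). The clock output factors Dbp and Hlf and the repressor Nr1d1 had log2 fold changes of -2.40 ± 0.38, -1.44 ± 0.24 and -1.57 ± 0.21, and the clock-controlled gene Ciart fell from 10.9 to 4.25 TPM. The list's adjusted p was 0.00101 by camera and the adjusted p = 0.150 with an estimated correlation.

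**Figure D2:**
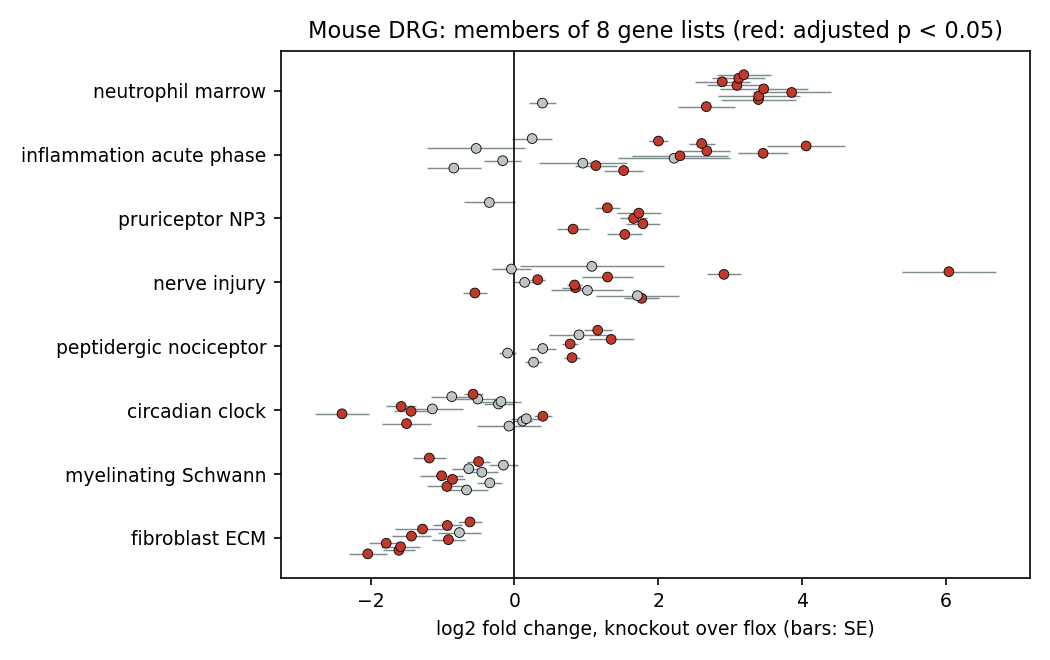
Log2 fold change (knockout over flox, horizontal axis) of every tested member of 8 gene lists in mouse DRG; each point is a gene, its bar is the SE, and red points have an adjusted p under 0.05. In the neutrophil list 9 of 10 genes lie to the right with red points, and in the fibroblast and matrix list 9 of 10 red points lie to the left.

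Lists with few called genes are given for completeness. The MHC class II list was called lower (adjusted p = 0.00560, adjusted p = 0.403 with an estimated correlation) with H2-DMa called over all genes (-0.58 ± 0.10) and 5 of 6 genes adjusted over the list alone. The list of C-fibre low-threshold mechanoreceptors was called lower at an adjusted p of 0.0489, with an adjusted p = 0.588 with an estimated correlation, with Gfra2 called over all genes (-0.86 ± 0.21) and 3 of 5 adjusted over the list alone; it was lost without flox library 1, 4, 5 or 7 and without knockout library 3, 4, 6 or 7 (adjusted p up to 0.146). The remaining lists were not called by camera. Among other pruriceptors (NP1 and NP2), 2 of 10 genes fell, Cd55 (-0.92 ± 0.17) and Lpar3 (-1.26 ± 0.24), with a list adjusted p of 0.169. Immediate early and stress genes had 2 called of 12, Jun (1.23 ± 0.14) and Junb (1.04 ± 0.14), and an adjusted p of 0.115. In the excitability list (adjusted p = 0.473), Kcnq3 and Cacna2d1 rose and Kcnk2 fell. In the lymphocyte list (adjusted p = 0.617), Jchain and Nkg7 rose by 2.81 ± 0.41 and 1.83 ± 0.42 while Ighm and Ms4a1 fell. In the mast cell list (adjusted p = 0.974), Hdc rose by 2.26 ± 0.37 and Mcpt4 had a log2 fold change of -2.38 ± 0.66. In the interferon list (adjusted p = 0.659), Oasl2 rose by 1.06 ± 0.12 while Bst2 and Isg15 fell.

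Oxidative phosphorylation genes (adjusted p = 0.145) included 3 of 13 that rose, Ndufs4, Ndufa4 and Uqcrc1. The macrophage list (adjusted p = 0.884) had Ptprc higher, and the satellite glia list (adjusted p = 0.884) had Cdh19 higher and Gfap lower. In the natriuretic peptide list (adjusted p = 0.884) Npr3 fell while Nppb rose, and 4 of 5 tested genes passed when adjusted over the list alone. In the large-diameter neuron list (adjusted p = 0.884) Ntrk3 fell. Map3k6 rose in the glucocorticoid list (adjusted p = 0.245), and Acta2 fell in the endothelial and mural list (adjusted p = 0.184). No gene was called among those of skeletal muscle (adjusted p = 0.152), adipocytes (adjusted p = 0.497) or spinal cord (adjusted p = 0.884). The skeletal muscle level varied between libraries, from 1.21 in knockout library 2 to 7.61 in flox library 6 on the log2(TPM + 1) scale.

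The genotype difference was compared between batches. Batch 1 alone gave 273 calls and batch 2 alone 2085. Over 14872 genes tested in both, 124 genes were higher in both (12.4 expected of independent lists, Fisher's exact p = 2.76e-104) and 37 lower in both (6.39 expected, Fisher's exact p = 2.50e-19). Fisher's test treats genes as independent, which they are not, so these p-values do not measure the spread between libraries. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.510 and a Spearman correlation of 0.444. The interaction of batch and genotype was called for 161 genes, with Nppb not among them (difference 0.40 ± 0.37, adjusted p = 0.735). Nts was among them: its log2 fold change was 0.80 ± 0.27 in batch 1 and 2.66 ± 0.23 in batch 2. Without the batch term 564 genes were called, and Nppb then had an adjusted p of 0.0994, outside the threshold. Y-linked transcripts stood clearly above the other libraries in knockout libraries 6 and 7, both of batch 2. No flox library reached their level, so sex cannot be told apart from genotype in that part of batch 2. Without these 2 libraries 1757 genes were called, with knockout library 5 as the only knockout library of batch 2.

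The second comparison asks whether the same gene, NPPB, and other DRG transcripts differ in monkeys whose skin was treated with SADBE. NPPB averaged 4.08 ± 0.925 TPM with SADBE and 1.05 ± 0.290 TPM with vehicle (SD, n = 3 each), and the 2 groups did not overlap. Its log2 fold change of 1.91 ± 0.73 did not pass the test over all genes (unadjusted p = 0.0281, adjusted p = 0.999 in edgeR). Interferon-response genes were lower with SADBE as a list, although no member passed by itself and the list did not hold with an estimated correlation. Vehicle library 1 shared the difference for part of the list, such as IFI44 and PSMB9, but its list mean of 4.27 (log2(TPM + 1)) lay below 4.47 and 4.34 in SADBE libraries 2 and 3, against 6.00 and 5.51 in the other vehicle libraries.

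NPPB was counted 29, 11 and 35 times in SADBE libraries 1 to 3, and 11, 8 and 7 times in vehicle libraries 1 to 3. In counts per 1e6 (CPM), the SADBE libraries held 1.29 (95% interval 0.866 to 1.86), 1.22 (0.609 to 2.18) and 1.99 (1.39 to 2.77). The vehicle libraries held 0.406 (0.203 to 0.726), 0.303 (0.131 to 0.597) and 0.511 (0.205 to 1.05). These are exact Clopper-Pearson intervals and cover counting error only. An exact two-sided permutation test on log2(TPM + 1) gave p = 0.1, the smallest that 3 against 3 libraries allow. No gene of the NP3 list passed: IL31RA stood at 2.20 ± 2.19 TPM with SADBE and 4.41 ± 3.06 TPM with vehicle, and OSMR at 13.9 ± 2.16 and 13.2 ± 7.64 TPM (SD, n = 3 each). By library, IL31RA stood at 4.73, 0.920 and 0.942 TPM in SADBE libraries 1 to 3. In vehicle libraries 1 to 3 it stood at 3.89, 7.70 and 1.65 TPM. SST, CYSLTR2 and HTR1F had log2 fold changes of -0.18 ± 0.59, -0.48 ± 0.61 and -0.17 ± 0.71. The list's camera adjusted p was 0.862.

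edgeR called 0 of 17988 monkey genes, against 550 at an unadjusted p under 0.05, and limma on TPM called 0, DESeq2 27 and voom with quality weights 3. The genes with the lowest p and non-overlapping groups, a condition that chance meets for 10% of genes, are named as values that did not pass in edgeR. Higher with SADBE were TRIL (27.5 and 3.45 TPM), the phosphatase PTPN11 (57.6 and 10.7 TPM), RASL11B (48.0 and 8.60 TPM) and ST3GAL1 (20.5 and 5.17 TPM). Lower were the chemokine CXCL11 (0.0420 and 9.92 TPM), ANGPTL7 (6.66 and 34.0 TPM), THRSP (5.68 and 166.7 TPM), BCL2A1 (0.925 and 9.79 TPM) and DGAT2 (4.67 and 28.5 TPM), the last an enzyme of triglyceride synthesis. The smallest unadjusted p among these genes was 0.000383 in edgeR, for TRIL. DESeq2 called all 9 of these genes, and voom with quality weights called TRIL and PTPN11. In the simulated monkey comparison 26 of the 51 calls of DESeq2 were false.

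camera called 2 of 25 lists in monkeys. Of 18 interferon-response genes none passed over all genes, while 2 passed when adjusted over the list alone. IFI44 averaged 20.7 ± 6.26 TPM with SADBE and 67.6 ± 33.8 TPM with vehicle, and PSMB9, an immunoproteasome subunit, 34.8 ± 5.83 and 101.5 ± 28.9 TPM (SD, n = 3 each). GBP2 averaged 11.8 and 43.9 TPM. The chemokine CXCL10 averaged 15.7 and 420.9 TPM, although vehicle library 1 held 13.0 TPM and overlapped the SADBE group. The list's mean log2 fold change was -1.31, with a camera adjusted p of 2.99e-09 and an adjusted p = 0.805 with an estimated correlation. None of 10 cell cycle genes passed; the list was lower at a camera adjusted p of 0.0384, with an adjusted p = 0.805 with an estimated correlation, and was lost without vehicle library 1 or 3 or SADBE library 1 (adjusted p of 0.245, 0.211 and 0.348).

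**Figure D3:**
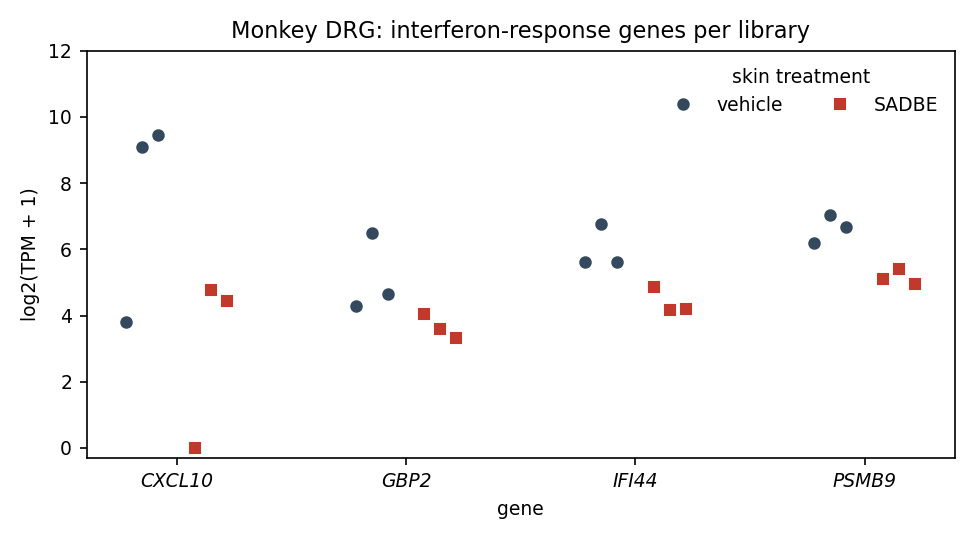
Level of 4 interferon-response genes in each monkey library, on the log2(TPM + 1) scale; circles are vehicle libraries and squares are SADBE libraries, 3 of each. The 3 SADBE libraries lie below the 3 vehicle libraries for GBP2, IFI44 and PSMB9, and the groups overlap for CXCL10.

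The other 23 lists were not called in monkeys. Those with the lowest camera adjusted p were fibroblast and matrix genes and adipocyte genes (0.0822 each), then neutrophil genes and acute-phase genes (0.0852 each), each lower on average with SADBE. Single libraries carried much of these lower means. Vehicle library 1 held 2110 TPM of the adipocyte gene FABP4 and 921.3 TPM of the neutrophil gene S100A9, against 282 to 367 TPM and 38.0 to 97.1 TPM in the other vehicle libraries. SADBE library 1 held 45.6 TPM of FABP4, against 345 and 444 TPM in the other SADBE libraries, and was the lowest of the 6 libraries in the mean of all 4 lists. Peptidergic nociceptor genes, cytokine receptor genes, macrophage genes and oxidative phosphorylation genes had an adjusted p of 0.131 each. Satellite glia and glucocorticoid genes stood at 0.294 each, endothelial and mural genes at 0.421, the natriuretic peptide list at 0.475 and immediate early genes at 0.567. Myelin genes stood at 0.713, and large-diameter neuron, nerve injury, clock and spinal cord genes at 0.813 each. Excitability genes stood at 0.853, NP1 and NP2 genes at 0.879, and C-fibre mechanoreceptor and lymphocyte genes at 0.882 each. Mast cell, MHC class II, erythroid and skeletal muscle lists had 2 tested genes each and were not tested as lists.

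The mouse and monkey comparisons were then set side by side over 12213 genes with the same symbol. With 0 monkey calls in edgeR there was no shared call. At an unadjusted p under 0.01 in both, 2 genes were higher in both (2.30 expected of independent lists) and 3 lower in both (3.42 expected), and Fisher's exact test gave p = 1 for each direction. The 5 genes, chosen after their values were seen, were Smim13 and Tmem254 (higher) and Cldn1, Lrrc75a and Tbx15 (lower). Across genes, which are not independent, the log2 fold changes had a Pearson correlation of -0.02 and a Spearman correlation of -0.01. The 947 genes called higher in mouse knockout had a median log2 fold change of -0.13 in monkeys, with a camera adjusted p of 0.252 and an adjusted p = 0.0183, in the same lower direction, with an estimated correlation. The 998 genes called lower in mouse knockout had a median of -0.10 (adjusted p = 0.252, and 0.668 with an estimated correlation).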

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

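The tests of depth, of the Y-linked libraries and of the neutrophil and matrix genes were chosen after the results were seen. The other splits of the samples and the test around Adam17 were set before their results were known.

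The Y-linked gene Ddx3y, which did not pass the filter and enters no comparison, was above the flox level in 2 knockout libraries of batch 2: it stood at 19.2 TPM in library 6 and 22 TPM in library 7, and at most 0.129 TPM in any flox library. The effect of genotype on Nts differed between the batches, with an interaction of 1.82 ± 0.36 on the log2 scale (batch 2 minus batch 1, adjusted p = 0.0264 in edgeR). It was 1 of 161 genes with such a difference. Without knockout libraries 6 and 7 the knockout side of batch 2 is library 5 alone, so no count is given for that fit. The Y-linked gene Uty, chosen after its values were seen, was among the 161 (4.43 ± 0.96, adjusted p = 0.0368). A sample far from the others in its group was found in 1 of 56 groups of gene values tested: flox library 6 held 4 counts of Fezf2 where the other flox libraries held 0, a gap of 0.75 of the group's range after centring within batch. With every other value at 0, centring fixes the gap at 0.75 whatever the count, so it says nothing about that library.

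The first pattern weighed was the number of genes called between knockout and flox. Of 100 within-batch splits of the 14 libraries, 1, the real one, gave 2423 genes, and the highest other split gave 1 gene. That is the smallest share that 100 splits allow, so chance is unlikely. The other splits mix the genotypes in at least 1 batch, which adds the genotype difference to their spread. With every library thinned to the smallest total, 2351 genes were called, so unequal totals by themselves do not account for the number of calls. That fit pooled both batches, and batch 2 alone gave 2085 calls. It therefore does not tell what the depth difference did to the calls of batch 1, or whether preparation differed there. Without knockout libraries 6 and 7, which held Y-linked reads, 1757 genes were called, 1463 of them among the 2423. Knockout library 5 was then the only knockout library of batch 2. Genes within 20 Mb of Adam17 were called in 32 of 138 cases, an odds ratio of 1.65 (95% interval 1.07 to 2.48) against genes elsewhere. Strain variants carried along with the targeted gene may therefore account for some of these 32 calls, which the width of the interval leaves open, and the genotype itself remains an open biological explanation. The mitochondrial share of counts also differed by genotype in batch 2 (0.734% to 1.03% in knockout, 1.40% to 1.76% in flox), and whether RNA quality contributes was not tested.

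Within batch 2 the real split was the 1 of 35 that gave as many as 2085 genes, and the highest other gave 0. That is the smallest share that 35 splits allow, so chance is unlikely there. The other splits mix the genotypes, which adds the genotype difference to the spread within their groups. Knockout libraries 6 and 7 of this batch held Y-linked reads at a level that no flox library reached, so sex may differ with genotype there. Within batch 1, 2 of 35 splits gave at least the 273 genes of the real one, so chance is not excluded for that batch by itself; the split of knockout libraries 1 to 3 and flox library 1 against the rest gave 464, which points to another structure among those 7 libraries. For the interaction, 4 of 100 splits gave at least 161 genes, and the highest other split gave 629. That split kept the real genotype groups in batch 2. In batch 1 it grouped flox libraries 2 and 3 with knockout libraries 2 and 4. The genotype difference of batch 2 can then be counted as an interaction. Such splits hold the genotype effect itself, so they cannot tell whether the 161 calls exceed chance.

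The number of called mouse lists at the preset correlation is a different matter: 21 of 100 splits gave at least the 12 lists of the real one, with 16 in the highest other, so chance is not excluded for that count. In monkeys there are 10 splits, too few for a share under 0.05. The real split gave 0 genes in edgeR (550 at an unadjusted p under 0.05; DESeq2 called 27 and voom with quality weights 3) and 2 lists. All 10 splits gave at least 0 genes, and 7 of the 10 gave at least 2 lists, with 1822 genes and 13 lists in the highest others. The split with 1822 genes set vehicle libraries 1 and 2 and SADBE library 1 against the other 3, which points to a structure of the samples other than treatment. The first 3 had the highest totals (27.1, 26.4 and 22.4 M). Vehicle library 3 and SADBE libraries 2 and 3 held 13.7, 9.02 and 17.6 M. Whether depth underlies this split was not tested, and no monkey fit has a term for it.

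The second pattern was the rise of neutrophil genes in knockout ganglia. More blood carried over with the tissue would raise erythroid genes alike. The neutrophil score rose by 2.98 (log2) while the erythroid score moved by -0.18. The difference between them had an exact permutation p of 0.00571 over 1225 within-batch splits. In the edgeR fit the 6 erythroid genes had a mean log2 fold change of 0.29, of the other sign, and an estimated correlation of 0.937 with each other. These values argue against a larger amount of blood as the whole cause, but do not bound a smaller share of it. They cannot speak to blood that holds more neutrophils at the same amount, because erythroid genes would then not rise. More whole bone marrow would raise genes of B-cell precursors alike. The 3 of 10 such genes that passed the filter (Cd79a, Cd79b and Ighm, which mature B cells also express and which the lymphocyte list holds) moved by -0.71, and the neutrophil score minus theirs had an exact permutation p of 0.000816, the smallest the splits can give. The other 7 could not be tested, and Jchain and Ighg1, which antibody-secreting cells express, rose, so marrow is not excluded. Marrow, cells of the granulocyte lineage inside the ganglion or its vessels, or a change of these genes in other cells may explain the rise; S100a8 averaged 2670 TPM in knockout and 264.9 TPM in flox.

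The third pattern was the fall of extracellular matrix genes. A lower share of fibroblasts by itself would lower all their transcripts alike. The 4 fibrillar collagens moved by -1.77 (log2) and Dcn, Lum, Pdgfra and Mgp by -1.04 (exact permutation p of the difference 0.00408). These collagens are also the 4 genes of the list with the lowest p, so the difference may come from that choice, and a lower share of fibroblasts is not excluded. Lower collagen transcription per cell and a shift between kinds of fibroblast also stay open.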

How the results depend on the processing

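The tests that left out pairs of knockout libraries or thinned the counts were chosen after the results were seen; the others were planned. Every mouse gene of the rule other than Adam17 kept its direction in every alternative that could be fitted, but calls were lost. Batch 1 alone lost Htr1f, Nts, Rps19-ps6, Serpina3m, Mfap4, Col2a1, Gxylt2 and Sfrp4, batch 2 alone Htr1f and Sfrp4, no batch term Htr1f, Gxylt2 and Cma1, and the replicate block Htr1f. Ftl2-ps and Rps19-ps6 were lost with limma at pseudocount 0.1, voom and without knockout libraries 6 and 7, and Ftl2-ps also with limma at pseudocount 1. The called mouse lists kept their direction, but batch 1 alone lost C-fibre mechanoreceptor, MHC class II and cell cycle genes, and fry the first and last of these. C-fibre mechanoreceptor genes were also lost with RLE, the replicate block, thinning, and without knockout libraries 6 and 7. Mouse calls numbered 564 with no batch term, 273 in batch 1 alone (the cause was not tested) and 940 at an adjusted p under 0.01; the other alternatives stayed within 1.5 times of 2423. Leaving out each library gave 1587 (without knockout library 5) to 3108. Nppb lay between 1.41 and 1.87, and without the batch term it was 1.79 but no longer called (adjusted p = 0.0994; range over its alternatives 9.00e-15 to 0.0994). Adam17, never called, turned to -0.062 in batch 1 alone and -0.068 without knockout libraries 6 and 7, and lay between -0.070 and 0.11 with 1 library left out. The interaction count fell to 21 without knockout libraries 6 and 7, but was 212 without 5 and 6 and 138 without 5 and 7 (chosen after seeing the data). Called mouse lists fell to 4 with an estimated correlation, and were 10 with fry. For the lists the cause was not tested.

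In monkeys, 27 genes were called by DESeq2 and 3 by voom with quality weights; the cause was not tested. NPPB lay between 1.30 and 2.27 and was never called; DESeq2 gave it no adjusted p. Called lists numbered 1 with no filter, 1 with the stricter filter, 0 with an estimated correlation and 0 with fry. They ranged from 2 to 7 with 1 library left out: 4 without vehicle 1, 6 without vehicle 2, 7 without SADBE 2 and 6 without SADBE 3. Uncalled NP3 genes changed sign: SST (0.17 and 0.18 with limma at pseudocounts 1 and 0.1; -0.62 to 0.40 with 1 library left out), CYSLTR2 (0.14 and 0.19 with limma; -0.76 to 0.23), OSMR (-0.37 to 0.53) and HTR1F (-0.37 to 0.20); for these lists and genes the cause was not tested. At an unadjusted p under 0.01, 5 genes were shared between species. No scaling moved the median of all genes by more than 0.1. The sex term was not run. NPPB had 7 to 35 counts a library, so counting error is part of its spread.

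Deviations of same-numbered libraries correlated at -0.39 to 0.17 in mice (own number best in 0 of 7), which gave no sign that the numbers pair the libraries. In monkeys they correlated at -0.41 to 0.32 (own number best in 1 of 3). With 3 libraries in each monkey group this cannot tell whether the numbers pair them, and the labels do not say. With the number as a block, 2103 mouse genes, 12 mouse lists, 0 monkey genes and 2 monkey lists were called; Nppb was 1.67 and NPPB 1.92, Adam17 was -0.0048 and SST 0.10, and 0 genes were shared between species.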

Other observations

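Except for Rps19-ps6, the genes named here were chosen after their values were seen, from the 30 lowest p-values of the mouse comparison, and no further test was run on them. Bdnf, a neurotrophin released by sensory neurons, rose by 3.10 ± 0.15 (log2 fold change ± SE), from 7.13 to 60.3 TPM, with 2.89 in batch 1 and 3.29 in batch 2. Fam210b, a mitochondrial protein gene, rose by 3.47 ± 0.14, with an adjusted p of 5.40e-10 in edgeR, the smallest of the comparison. Galnt6, a glycosyltransferase gene, rose by 4.07 ± 0.19, and Tifa, an adaptor of inflammatory signalling, by 3.03 ± 0.15. Alkal2, a ligand of the ALK receptor, rose from 5.89 to 155.2 TPM, and Sting1, the adaptor of cytosolic DNA sensing, from 4.45 to 42.4 TPM. The neuropeptide precursor Vgf rose by 1.73 ± 0.15, and Cckar, a cholecystokinin receptor, by 1.86 ± 0.16.

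Racgap1, Tk1 and Tuba1c rose by 3.03 ± 0.20, 1.87 ± 0.16 and 1.47 ± 0.12. Nt5e, an enzyme that makes extracellular adenosine, rose by 1.91 ± 0.15, and Rspo2, a Wnt signal enhancer, by 1.70 ± 0.15. Outside that set, the pseudogene Rps19-ps6 read at 99.4, 31.1, 0, 61.0, 2.71, 420.7 and 220.2 TPM in knockout libraries 1 to 7, so its rise was carried by 5 of the 7 libraries. These are values without an explanation.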
